A study of Mus musculus with 2 samples.

How the data were processed

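The samples were 2 libraries of total RNA from the gastrocnemius muscle of 8-week-old C57BL/6 mice. Per the labels, 1 library came from Cipc flox/flox mice, which carry the Cipc gene flanked by loxP sites, and 1 from Cipc scKO mice. The series title describes a deletion of Cipc specific to satellite cells, the stem cells of skeletal muscle, so scKO was read as that genotype. The title also names mdx mice, a model of muscular dystrophy. The labels and the design text of these libraries name neither mdx nor any injury, so the libraries were treated as not mdx, which remains uncertain. The labels do not say whether RNA of several animals was pooled. Per the labels' protocols, RNA integrity was inspected on a Bioanalyzer, the RNA was purified on beads, and libraries were made with a VAHTS Universal V6 kit for Illumina sequencing.

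The deposited table of gene counts holds whole-number counts for 34745 Ensembl genes in each library, with no rows outside genes. Per the submitters' processing notes, the tools were CASAVA, HISAT2 2.0.4 and StringTie 1.3.0, and the genome build was GRCm38; the notes used here give no role or order for them. The annotation release, the counting options, the treatment of reads that match several genes and the strand setting were not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical copies could therefore be divided between genes in a way that cannot be checked from the counts. The deposited FPKM values, per the file headers given as 1 column per library, were tested against the counts. The length implied by each FPKM, the gene's count and the library's total count was the same in both libraries to within 0.0198% for genes with at least 20 flox/flox counts and a count in scKO. That length lay within 1% of the summed distinct exons of the gene in GENCODE M21 for 7909 of 11548 genes (68.5%). Its median was 1.24 times the length of the merged exons. For these genes the FPKM values hold no measurement that the counts lack, and the counts were used for the main values.

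Gene names came from a reference table, which named 34267 of the 34745 identifiers; the remaining 478 held 0.0302% of the flox/flox counts and 0.0332% of the scKO counts. Gene positions, exon overlaps, 3′ UTRs and transcript sequences came from GENCODE M21, which is on the same build, GRCm38. The total count was 14727219 in the flox/flox library and 13842100 in the scKO library. A single count corresponded to 0.0679 and 0.0722 CPM, and the upper limit allowed by 0 counts, 3 counts, to 0.204 and 0.217 CPM.

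Library sizes were scaled with the TMM method of edgeR 4.0.16 under R 4.3.3. For each gene the log2 ratio of scKO over flox/flox was computed with a prior count of 0.5, and an exact conditional binomial (Clopper-Pearson) 95% interval of the ratio was computed from the counts. These intervals and the limits for 0 counts cover counting error only; PCR copies and differences between animals are not in them. With 1 library per group, no dispersion between animals was estimated and no p-value was computed across genes. A gene was tested where its summed count was at least 20. It was counted as at least 2-fold higher or lower where the ratio of scaled counts was at least 2 or at most 0.5 and the interval excluded 1. Folds against 0 counts were computed against 3 counts and are lower bounds that leave out the counting error of the other library. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and matplotlib 3.10.9 for the plots.

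Gene lists, 31 in number, were fixed before the data were examined, together with the tests, the alternatives listed first below and the rule for named genes. They cover the clock, satellite cells, myogenesis, fibre types, matrix, MAP kinase signalling, metabolism, stress and the other cell types a whole muscle can hold. Checks of sex, blood and ribosomal protein transcripts were included. The median log2 ratio of a list's tested members was placed among the medians of 10000 random gene lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart below the 2.5th or above the 97.5th percentile. Lists with fewer than 5 tested members are given as values only. The 31 lists hold 529 genes, 8 of which belong to more than 1 list. An interval for each list median was taken from the order statistics of its members. The named genes were Cipc, Pax7, Myod1 and Sp1 in every case. Among genes with at least 100 counts in the higher library, the 10 highest and 10 lowest log2 ratios were added, leaving out predicted gene models. From each list, up to 4 members with the largest absolute log2 ratio were added. Further genes named in the text were chosen after their values were seen; these are the remaining list members, the neighbours of Cipc and the partners of overlapping genes. Some list members are not reported here by name.

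The procedure was tested on simulated counts of the scKO against the flox/flox library over 12647 genes. The counts were independent Poisson draws, without differences between animals and without shared regulation of genes. The rates below therefore cover counting error only and are not the rates of false calls in the real libraries. Of genes changed by 1.5-fold, 2 of 50 were called; of those changed by 2-fold, 23 of 49; by 3-fold, 48 of 49; and by 4-fold, 48 of 49. Of 12450 genes simulated without change, 61 were called. Of 200 random lists of 20 genes, 12 stood apart, as did all 100 lists raised by 0.3 on the log2 scale.

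The alternatives were total-count scaling, size factors of DESeq2 1.42.0, upper-quartile scaling, and total counts without mitochondrial genes and the 20 most abundant genes. The deposited FPKM on the scale log2(FPKM + 0.1), count minimums of 10 and 100, no minimum, fold limits of 1.5 and 4 and a prior count of 5 were also tried. So were counts without the interval requirement or with the whole interval beyond 2-fold, and lists without genes that belong to other lists. Alternatives chosen after seeing the data were counts without genes that overlap another on the same strand, and list medians corrected for GC content and transcript length. A quasi-likelihood test had been planned in case the files held several animals per group. Each group had 1 column, so it was not applicable.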

Results

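Gene expression was measured by RNA sequencing of whole gastrocnemius muscle in 1 Cipc flox/flox library and 1 Cipc scKO library from 8-week-old C57BL/6 mice. Cipc encodes the CLOCK-interacting pacemaker protein, an inhibitor of the transcription factor pair CLOCK and BMAL1. The series title concerns mdx mice, which lack dystrophin, but the labels of these libraries do not say mdx, so whether the muscles were dystrophic is not settled here. By the series title, the comparison of scKO with flox/flox asks how deleting Cipc in satellite cells alters the RNA of the muscle. The libraries held 14727219 counts over 16375 genes (flox/flox) and 13842100 counts over 16155 genes (scKO). Mitochondrially encoded transcripts took 25.7% of the counts in each, and the 20 most abundant genes took 42.6% and 41.5%. With 1 library per genotype, none of the differences below has a replicate check: they compare these libraries, not the genotypes. Brackets after the ratio of a gene give 95% intervals, which cover counting error only. Brackets after a median over genes give 95% intervals from the order statistics of those genes, and so reflect the spread among them.

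Cipc itself was 5.72-fold lower in the scKO library, with 658 counts in flox/flox and 111 in scKO (log2 ratio −2.51, −2.82 to −2.22). The gene (ENSMUSG00000034157) lies on the plus strand of chromosome 12 at 86947043 to 86965362 in GRCm38. The counts cover the whole gene, so the value does not show which exons the remaining reads came from. Satellite cells are a small part of whole muscle, where their marker Pax7 had 69 and 39 counts, and the share of Cipc RNA that comes from them was not measured. The size of the Cipc ratio therefore does not show that the loss was limited to satellite cells. The next gene on the same strand, Tmem63c (ENSMUSG00000034145, chromosome 12, 87021340 to 87090043), begins after a gap of 55977 bp. It had 0 counts in flox/flox and 118 in scKO, at least 40.8-fold higher when set against 3 counts in flox/flox. Zdhhc22 and Ngb, on the opposite strand beside Tmem63c, had 0 counts in both libraries. Of the other 14 tested genes within 500 kb of Cipc, the median log2 ratio was −0.038 (−0.15 to 0.32). Irf2bpl, the nearest tested gene upstream, stood at −0.06 (−0.26 to 0.15), and Pomt2, the nearest tested one beyond Tmem63c, at −0.29 (−0.67 to 0.08). Farther downstream, 3 genes had intervals above 0: Noxred1, on 9 and 20 counts, was over 2-fold higher (1.16, 0.0031 to 2.52), Vipas39 stood at 0.39 (0.047 to 0.73) and Ahsa1 at 0.18 (0.068 to 0.30).

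**Figure D1:**
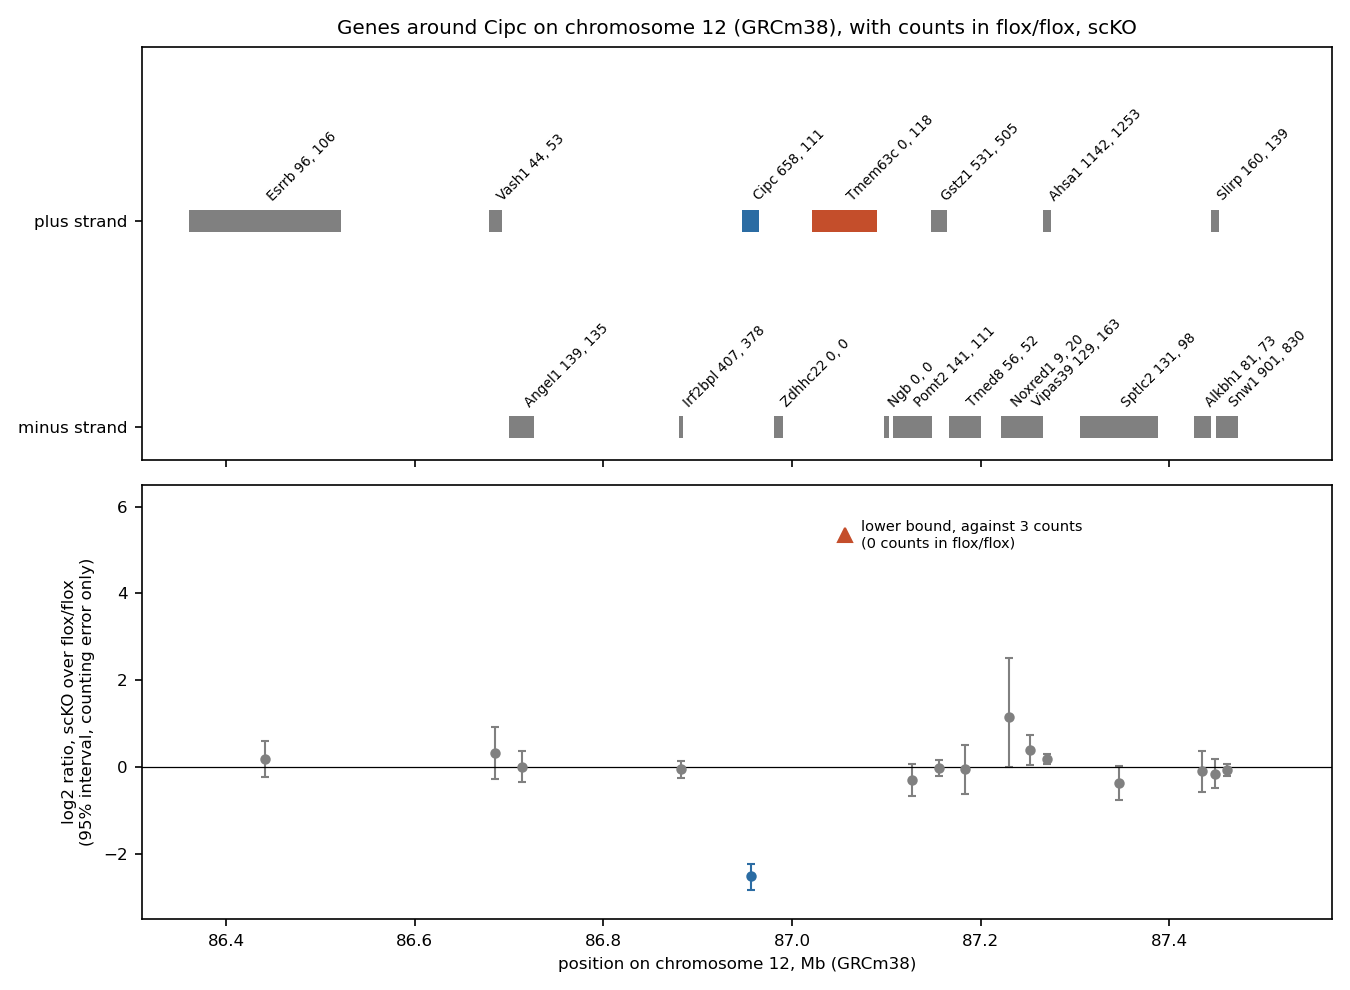
Genes within 500 kb of Cipc on chromosome 12 (position in Mb, GRCm38), drawn to scale by strand with their counts in flox/flox and scKO, above the log2 ratio of scKO over flox/flox of each tested gene. Bars are 95% intervals for counting error, and the triangle is Tmem63c against 3 counts in flox/flox (5.35). Cipc lies at −2.51 and Tmem63c is the single gene of the window above 2 on this scale.

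The satellite cell markers did not stand apart as a group. The transcription factor Pax7, which marks satellite cells (ENSMUSG00000028736, chromosome 4, 139737062 to 139833528), had 69 counts in flox/flox and 39 in scKO (log2 ratio −0.76, −1.38 to −0.19). Hes1, a Notch target, had a log2 ratio of −0.73 (−1.04 to −0.43). Myf5 stood at 0.61 (−0.19 to 1.45) and Cxcr4 at 0.33 (−0.63 to 1.32), both with intervals that include 0. The median over 16 tested markers was 0.021, at percentile 58.0 of random lists, and 14 of the 16 intervals included 0.

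Some regulators and other genes of muscle differentiation were lower in the scKO library. Myod1, the myogenic determination factor (ENSMUSG00000009471), had 201 and 130 counts (log2 ratio −0.58, −0.91 to −0.25). Myogenin (Myog) had a log2 ratio of −1.17 (−1.79 to −0.59), the cardiac α-actin gene Actc1 −1.12 (−1.17 to −1.07), and Mef2c −0.82 (−0.88 to −0.77). The regulators Myf6 (−0.15, −0.26 to −0.05), Mef2d (−0.11, −0.19 to −0.04) and Mef2a (−0.08, −0.17 to 0.01) moved less. The cell cycle inhibitor Cdkn1a was higher, at 0.65 (0.24 to 1.07). Of 15 tested members of the list of myogenic differentiation and regeneration, 7 had intervals below 0 and 1 above. The median of −0.11 lay within the random lists (percentile 5.25). With a count minimum of 100 the list stood below them, with a median of −0.15 at percentile 1.54. Myog also belongs to the denervation and neuromuscular junction list, whose median was 0.025 (percentile 58.7). In that list the acetylcholine receptor subunit Chrnb1 stood at −0.62 (−0.84 to −0.40), Hdac4 at −0.43 (−0.63 to −0.24) and Dok7 at 0.50 (0.19 to 0.81). The cell cycle list had 11 tested members of 25 and a median of 0.060 (percentile 72.6). Mitotic genes were among those with too few counts to be tested. Most of these had fewer counts in scKO: Ccna2 (11 and 3 counts), Bub1b (8 and 4), Top2a (7 and 2) and Plk1 (5 and 0). So did Bub1 (4 and 0), Ccnb1 (3 and 0), Cdc20 (3 and 2) and Aurkb (1 and 0). Cdk1 (3 and 6) and Birc5 (2 and 3) had more. The median therefore says little about mitotic genes. The proliferation marker Mki67 of this list had 18 and 4 counts (−1.99, −4.14 to −0.52, and −0.78 on the FPKM scale), while the intervals of Mcm5, Mcm6 and Rrm2 included 0, at 0.69, −0.63 and 0.47.

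Core clock genes did not move in a common direction. Nr1d1, which encodes the repressor REV-ERBα, was higher in scKO, with a log2 ratio of 0.80 (0.69 to 0.92), and the output gene Dbp was also higher, at 0.52 (0.44 to 0.61). Ciart and Nfil3, a repressor of the same promoter elements that DBP binds, were lower, at −0.86 (−1.22 to −0.52) and −0.41 (−0.65 to −0.17). Clock and Arntl, which encode the proteins CLOCK and BMAL1, stood at 0.10 (−0.13 to 0.33) and −0.05 (−0.59 to 0.50). Over 21 tested clock genes the median was 0.00084 (percentile 44.0), with 6 intervals above 0, 5 below and 10 that include it. The time of day at which the muscles were taken is not given in the labels.

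Transcripts of both fibre types were slightly lower in the scKO library. For the slow fibre list the median of 16 genes was −0.26 (−0.38 to −0.0038), below every random list, with 11 intervals below 0 and 1 above. Its largest ratios were those of the Z-disc protein gene Csrp3 (−1.04, −1.16 to −0.93), phospholamban (Pln, −0.83, −1.55 to −0.17), sarcolipin (Sln, −0.47, −1.27 to 0.30) and Ankrd2 (−0.38, −0.47 to −0.29), and Myh7 stood at −0.27. For the fast fibre list the median of 17 genes was −0.16 (−0.18 to −0.049), again below every random list, with 15 intervals below 0 and 2 above. Tpm1 had a log2 ratio of −0.40 (−0.41 to −0.39), Tnnt3 −0.28 (−0.29 to −0.27) and Pgam2 −0.21 (−0.24 to −0.18). Myh1, the fast IIx myosin, was an exception at 0.27 (0.26 to 0.29), while Myh4, the fast IIb myosin, stood at −0.16. Their counts are high, with 214002 and 156487 for Tpm1, so the narrow intervals say little about how much 1 muscle differs from another.

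Collagens and several other matrix genes were lower in scKO. The median of 21 tested genes of the extracellular matrix and fibrosis list was −0.28 (−0.46 to 0.14), below every random list. Of these genes, 12 had intervals below 0 and 2 above. Fibrillin 1 (Fbn1) had a log2 ratio of −0.78 (−1.01 to −0.55), Col3a1 −0.62 (−0.71 to −0.52), Sparc −0.58 (−0.66 to −0.50) and Col5a2 −0.55 (−0.79 to −0.32). Fn1 (0.25, 0.06 to 0.44) and Eln (0.44, 0.14 to 0.74) were the members with intervals above 0. Markers of fibro-adipogenic progenitors, the mesenchymal cells of muscle, had a median of −0.13 (−0.25 to 0.051) over 14 genes (percentile 0.81), with 7 intervals below 0 and 7 that include it. Pdgfra stood at −0.45 (−0.74 to −0.17), Clec3b at −0.38 (−0.63 to −0.13), Cd55 at −0.23 (−0.37 to −0.09) and Dpp4 at −0.25 (−0.80 to 0.30). The tendon list, another source of collagen, had a median of 0.14 over 9 genes (percentile 82.3). Its best counted members, Thbs4 (0.14, −0.10 to 0.39) and Fmod (−0.063, −0.36 to 0.23), had intervals that include 0. The largest ratios, on 30 counts or fewer per library, were those of Cilp2 (−1.03, −2.13 to −0.06), Mfap4 (−0.93, −1.95 to −0.01), Kera (1.13, 0.16 to 2.23) and Col11a1 (1.72, 0.32 to 3.61, and 0.59 on the FPKM scale).

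Immediate early and ERK-responsive genes had a median of −0.20 (−0.43 to 0.0095) over 25 genes (percentile 0.07), with 11 intervals below 0 and 1 above. Junb stood at −0.71 (−0.91 to −0.53), Atf3 at −0.78 (−1.12 to −0.45), Fos at −0.57 (−0.73 to −0.40) and Egr3, with few counts, at −0.83 (−2.21 to 0.38). The growth factor-induced gene Ier3 was the exception at 0.80 (0.36 to 1.25). Of the tested Dusp, Spry and Spred genes in the list, Dusp6 stood at 0.03 (−0.25 to 0.31) and Spry2 at 0.04 (−0.33 to 0.41). Spred1 (0.08, −0.27 to 0.43), Spry4 (0.29, −0.13 to 0.71) and Dusp4 (0.43, −0.69 to 1.60) also had intervals that include 0. Dusp1 was lower, at −0.29 (−0.39 to −0.19). Components of MAP kinase pathways and Sp factors had a median of 0.015 over 20 genes (percentile 54.2), but 3 single members were over 2-fold apart. The transcription factor gene Sp1 (ENSMUSG00000001280) had 31 counts in flox/flox and 293 in scKO, 9.79-fold higher (log2 ratio 3.27, 2.76 to 3.88). Mapk14, which encodes p38α, was higher at 1.34 (1.20 to 1.48), and Nras was lower at −1.36 (−1.66 to −1.07). Sp3 stood at 0.38 (0.15 to 0.61).

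The atrophy and autophagy list had a median of −0.10 (−0.25 to 0.15) over 19 genes (percentile 1.05), with 8 intervals below 0 and 6 above. The ubiquitin ligase genes Fbxo32 and Trim63 stood at −0.27 (−0.34 to −0.19) and −0.25 (−0.35 to −0.16), Eda2r at −0.58 (−0.88 to −0.29) and Fbxo21 at −0.39 (−0.70 to −0.09). Ddit4 and Klf15 were higher, at 0.49 (0.37 to 0.61) and 0.47 (0.29 to 0.65). In the list of heat shock and muscle stress, with a median of −0.0088 over 19 genes (percentile 39.0) and 3 intervals above 0 and 6 below, the metallothionein genes Mt1 and Mt2 were higher, at 0.89 (0.62 to 1.17) and 0.72 (0.36 to 1.09). Hspb7 was lower, at −0.48 (−0.54 to −0.43), and Ankrd1 stood at −0.47 (−0.98 to 0.02).

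Nuclear genes of oxidative phosphorylation were slightly higher in scKO. The median of 29 genes was 0.096 (0.033 to 0.14) at percentile 99.9, with 18 intervals above 0 and 2 below. Cox8b stood at 0.30 (0.20 to 0.40), Cycs at 0.30 (0.06 to 0.53), Ndufs3 at 0.26 (0.17 to 0.35) and Ndufa1 at 0.21 (0.06 to 0.37). The median of 13 mitochondrially encoded genes was −0.038 (percentile 17.3) and took the opposite sign, at 0.00048, with total-count scaling; mt-Nd6 stood at 0.52, mt-Nd3 at 0.20, mt-Nd5 at −0.11 and mt-Nd1 at −0.074. Fatty acid oxidation and PPAR targets had a median of 0.023 over 21 genes (percentile 69.9). Within that list Pdk4, the kinase that inhibits pyruvate dehydrogenase, was lower at −0.90 (−0.95 to −0.84), as were Hadhb at −1.02 (−1.18 to −0.86) and Ucp3 at −0.48 (−0.58 to −0.38), and Ppara was higher at 0.47 (0.08 to 0.87). Glycolysis and glycogen genes had a median of 0.016 over 19 genes (percentile 70.6), with Gapdh at −0.26, Pgk1 at −0.25, Gbe1 at 0.29 and Hk1 at −0.30 (−0.73 to 0.13). The dystrophin complex list had a median of 0.077 over 15 genes (percentile 92.3), with no interval below 0 and 7 above. Sntb1 stood at 0.96 (0.49 to 1.44), Nos1 at 0.68 (0.49 to 0.87), Dag1 at 0.38 (0.30 to 0.46) and Sgcd at 0.28 (0.00 to 0.55).

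Among the other cell types of a whole muscle, erythroid transcripts had a median of −0.38 (−0.59 to 0.87) over 7 genes (percentile 0.11), with 5 intervals below 0 and 2 that include it. The α-globin gene Hba-a1 stood at −0.48 (−0.70 to −0.27), the β-globin gene Hbb-bt at −0.42 (−0.74 to −0.10) and Alas2 at −0.59 (−1.10 to −0.11). The globin genes together took 138 CPM in flox/flox and 109 CPM in scKO; reads that match several of these near-identical genes could be divided among them. Endothelial markers had a median of 0.13 (−0.015 to 0.23) over 15 genes (percentile 98.1), with 5 intervals above 0, none below and 10 that include it. Flt1 stood at 0.45 (0.32 to 0.58), Tek at 0.33 (0.08 to 0.58), Fabp4 at 0.23 (0.15 to 0.32) and Vwf at 0.27 (−0.01 to 0.55). This list no longer stood apart once ratios were corrected for GC content and transcript length (median 0.12, percentile 97.3).

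The remaining lists lay within the random lists. Smooth muscle and pericyte markers had a median of 0.098 over 11 genes (percentile 89.8), with Cnn1 at −1.99 on 18 and 4 counts (−1.30 with a prior count of 5), Higd1b at −0.93, Myl9 at −0.29 and Tagln at 0.26. Adipocyte markers had a median of 0.097 over 12 genes (percentile 84.6). Scd1 stood at 0.49 (0.37 to 0.62) and Dgat2 at 0.47 (0.34 to 0.61), while Cidea and Retn had under 20 counts in each library. Schwann cell and nerve markers had a median of 0.055 over 10 genes (percentile 70.5), with Sox10 at −1.48 (−2.81 to −0.40) and Pmp22 at −0.22 (−0.41 to −0.040) the members with intervals below 0. Macrophage and monocyte markers had a median of 0.031 over 17 genes (percentile 64.4), with 2 intervals above 0, 2 below and 13 that include it. Cd163 (0.57, 0.14 to 1.01) and Lyve1 (0.65, 0.17 to 1.14) were above 0, and Cd74 (−0.54, −0.78 to −0.30) and C1qc (−0.58, −1.03 to −0.15) below. The largest ratio, that of Cd14 on 15 and 6 counts, was −1.20 (−2.92 to 0.18). The interferon list had a median of 0.14 over 19 genes (percentile 94.5), with 5 intervals above 0 and none below, in which Rsad2 (19 and 64 counts, 1.78, 1.05 to 2.62) and Ifit3 (27 and 54 counts, 1.04, 0.36 to 1.77) were over 2-fold higher. Cytoplasmic ribosomal protein genes had a median of −0.061 over 25 genes (percentile 8.56). Rps6 had 12 and 9 counts and Rpl13 had 28 and 20. These genes have near-identical copies in the genome, and how reads that match several genes were counted is not given, so their counts are uncertain.

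Lists with fewer than 5 tested members give values only. Of the lymphocyte markers, the immunoglobulin gene Ighm had 772 and 1717 counts (log2 ratio 1.20, 1.08 to 1.33) and Ptprc 39 and 34. The B cell genes Cd79a (2 and 3 counts) and Igkc (3 and 5) were near 0 in both libraries. None of the neutrophil markers reached 20 counts. Of the keratinocyte markers, Krt10 and Sfn each had 11 and 12 counts and Perp 30 and 17. Xist had 1 count in each library and the Y-linked genes were expressed in both, Ddx3y with 895 and 1235 counts, Eif2s3y with 896 and 1006, Uty with 243 and 270 and Kdm5d with 271 and 298.

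**Figure D2:**
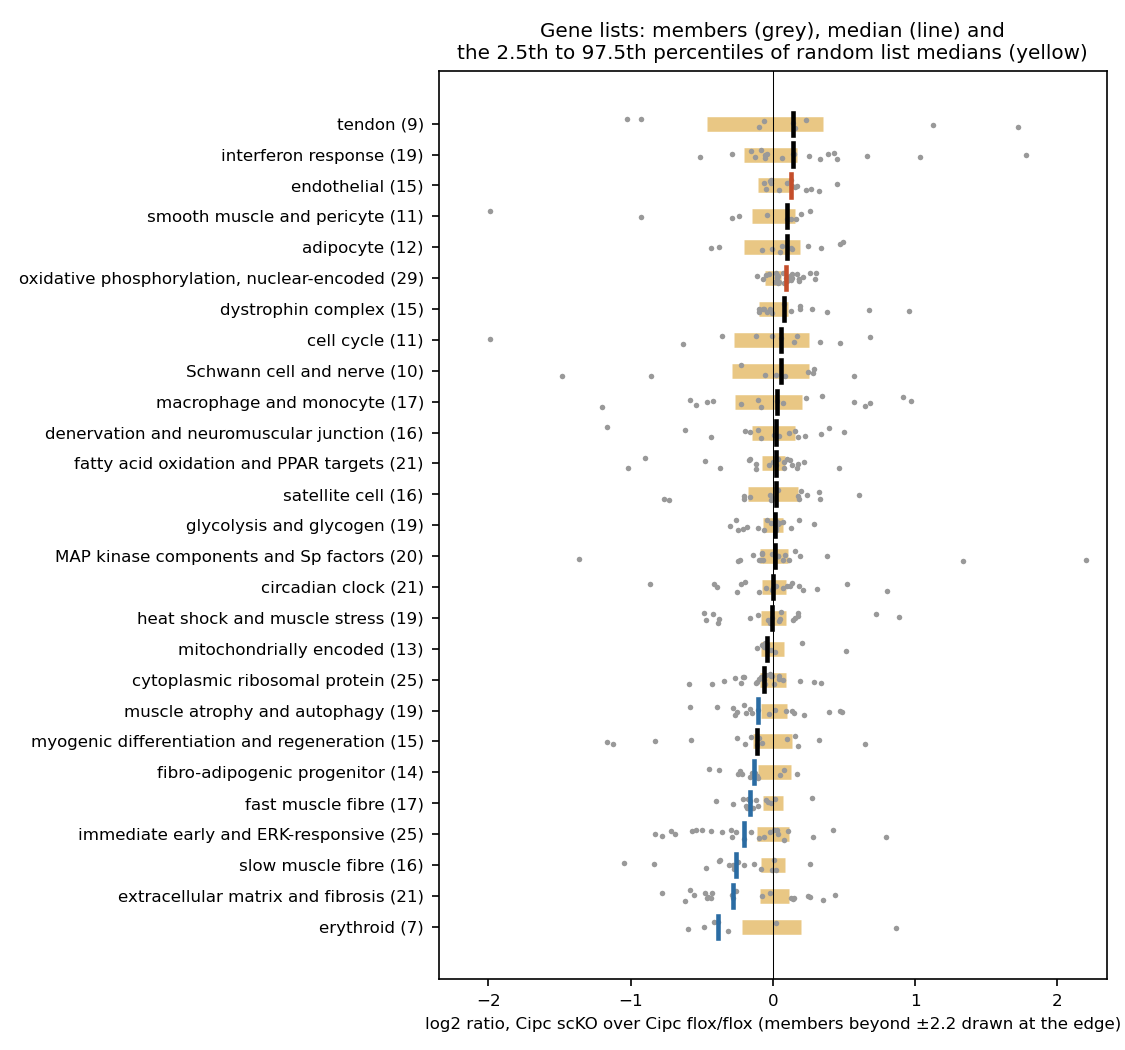
Log2 ratios of scKO over flox/flox for the 27 gene lists with at least 5 tested members (number of tested members after each name), with each member as a grey point, the list median as a vertical line and the middle 95% of matched random list medians as a yellow bar. Medians below the random lists are blue (7 lists), those above are red (2 lists), and the 1 member beyond 2.2 is drawn at the edge.

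Of the 27 lists that could be placed, 7 lay below, 2 above and 18 within the random lists. If each list held genes drawn at random, 1.35 would stand apart. The members of a real list are not independent of each other, so 1.35 is no chance rate for these lists. The percentiles describe these libraries.

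Of 12662 tested genes, 189 (1.49%) were at least 2-fold higher and 242 (1.91%) at least 2-fold lower in scKO. The share called in either direction was 10.6% among genes with a summed count of 20 to 100, 1.47% from 100 to 1000, 0.876% from 1000 to 10000 and 0.426% above that, where Actc1 was the single gene. Among the 8243 genes with at least 100 counts in the higher library, 48 were higher and 60 lower. The quartiles of the log2 ratio over all tested genes were −0.18 and 0.17. Requiring the whole interval to lie beyond 2-fold left 46 higher and 51 lower.

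Among genes with at least 100 counts other than predicted gene models, the highest ratio after Tmem63c was that of Lrch4 (7 and 206 counts, 30.5-fold), whose exons overlap the gene model Gm20605 on the same strand. That model went the other way, with 237 and 131 counts, and how reads of overlapping genes were divided is not given, so the value of Lrch4 alone (log2 ratio 4.83, and 3.82 on the FPKM scale) is uncertain. The log2 ratio of both summed was 0.52 (0.28 to 0.76). Synpo2, an actin-binding Z-disc protein gene, had 280 counts in flox/flox and 6242 in scKO, 23.1-fold higher (20.5 to 26.1). Sp1 followed, and then Akap2, at 6.47-fold, which shares exons with Pakap and stood at a log2 ratio of 1.12 (0.92 to 1.33) when summed with it. The tight junction gene Cldn12 was 5.08-fold higher, the kinase gene Nek7 4.14-fold (597 and 2384 counts), Pja1 4.02-fold, Selenoi 3.96-fold and Tmed2 3.81-fold.

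The lowest ratio among these genes was that of the histone gene Hist2h2aa1, with 594 counts in flox/flox and 0 in scKO, at least 191-fold lower when 3 counts are taken for scKO. Summed with Gm20634, which overlaps it on the same strand, it stood at a log2 ratio of −3.57 (−4.02 to −3.18). Its copy Hist2h2aa2 had 115 and 116 counts and so did not gain what Hist2h2aa1 lacked. How reads that match several copies were counted is not given, which leaves the exact value uncertain. Tmem127 was 9.87-fold lower (552 and 54 counts), Zbtb37 9.81-fold and Tmem245 8.34-fold. On the FPKM scale, with its pseudocount of 0.1, the log2 ratio of Zbtb37 was −1.90 in place of −3.26. Tead1, a transcription factor gene of the Hippo pathway, was 9.72-fold lower, with 3050 and 303 counts (8.63 to 11.0). The Polycomb gene Phc3 was 6.85-fold lower, Cipc 5.72-fold, Lrrc61 5.36-fold, Usf3 5.24-fold and the endocytic kinase gene Aak1 5.14-fold. Of the genes at least 2-fold apart with at least 100 counts, 104 had an annotated 3′ UTR, Cipc and Sp1 among them. The longest 3′ UTRs of these genes had a median of 2448.5 nucleotides, against 1471.5 in random sets matched on expression. That comparison was chosen after the ratios were seen.

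**Figure D3:**
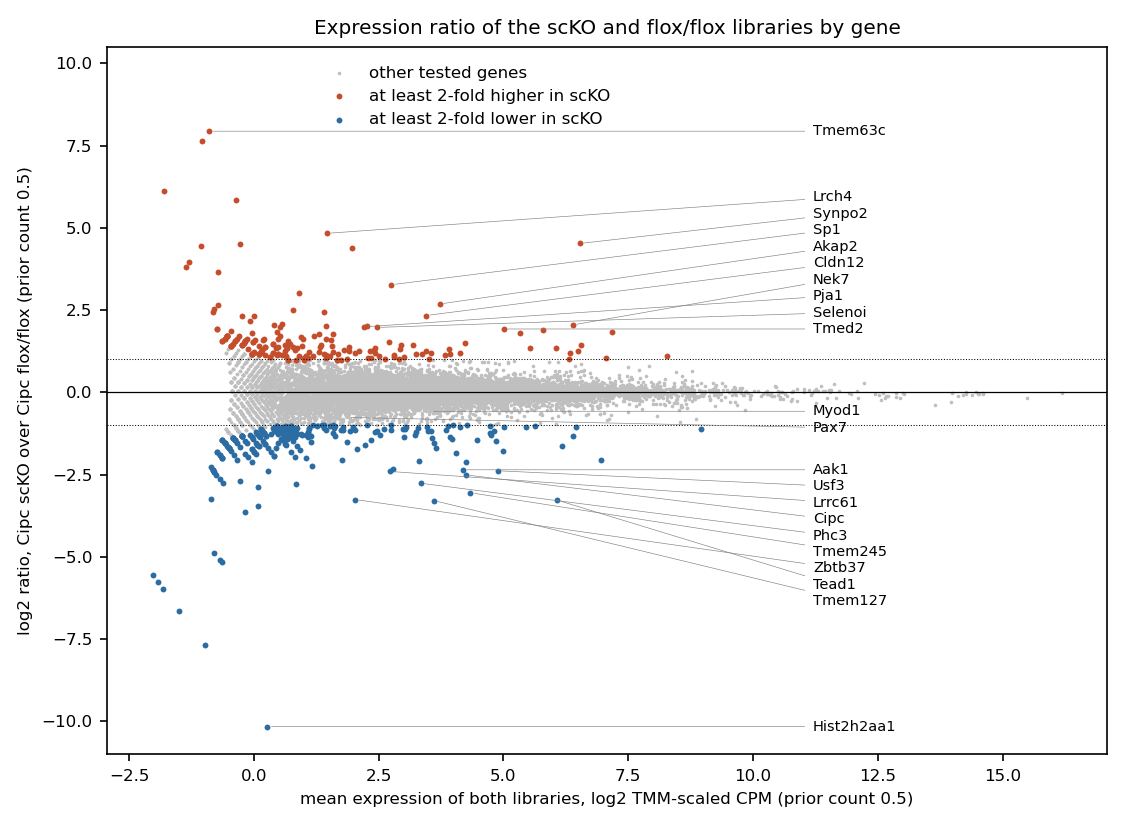
Log2 ratio of scKO over flox/flox against mean expression (log2 TMM-scaled CPM, prior count 0.5) for the 12662 tested genes, with genes at least 2-fold higher in red and at least 2-fold lower in blue. Dotted lines mark 2-fold, and the 10 highest and 10 lowest genes with at least 100 counts, without predicted gene models, are named beside Pax7 and Myod1. Cipc lies at −2.51 and Synpo2 at 4.53.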

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

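The correction for GC content and length and the count without overlapping genes were chosen after the data were seen; the other alternatives were chosen before. Cipc kept its log2 ratio within its counting interval under every scaling and with FPKM. The scalings differ by far less than the width of that interval, and the FPKM rest on the same counts. This is therefore no separate check of the Cipc ratio. The scalings shifted all ratios by −0.048 to −0.028 on the log2 scale relative to total counts and kept both counts of 2-fold genes within 1.5 times, as did a count minimum of 10, no interval requirement and leaving out overlapping genes (155 higher, 204 lower). A minimum of 100 counts gave 58 higher and 68 lower, and no minimum gave 369 lower, since fewer or more genes of low count were tested. A limit of 1.5-fold gave 440 and 522, a limit of 4-fold 33 and 51, and whole intervals beyond 2-fold 46 and 51. Without an interval requirement the FPKM scale gave 127 higher and 128 lower, against 225 and 304 from counts. The FPKM scale adds a pseudocount of 0.1, which draws the ratios of genes with low FPKM toward 0. How much of the gap comes from it was not tested. Among list medians, glycolysis and glycogen moved to 0.054 with total counts and with FPKM, and mitochondrially encoded genes to −0.078 with the GC and length correction; both stayed within the random lists. Position changed for 2 lists, the endothelial and the myogenic one; the cause was not tested. Of 810 values of the 135 other named genes, 778 stayed within their counting intervals, 32 moved outside and none changed direction among those with an interval on 1 side of 0. These values also rest on the same counts, so they are no separate check either. No paired analysis was possible because each group held 1 library. Depth limits genes of low count: ratios lay a median of 0.40 (log2) from the centre at summed counts of 20 to 100 and 0.086 above 10000.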

Other observations

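All tests of explanations in this part were chosen after the results were seen, on the same 2 libraries. Whether any pattern belongs to the genotype or to the animals or dissections was not tested, since each genotype had 1 library.

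There were 108 genes at least 2-fold apart with at least 100 counts, and how many would differ between muscles of 1 genotype is not known from these libraries. Exchange of reads between genes that overlap on the same strand is argued against for most of them, since 97 of the 108 have no such overlap in GENCODE M21. The strand setting of the counts is not given, and exchange with genes on the opposite strand was not tested. For the 7 genes with a tested partner it may account for part of the pattern: in 5 of them (Lrch4, Akap2, Gm38394, Gm28551 and Gm20431) the partners went the opposite way with an interval that excludes 0, though the amounts were close for Gm38394 alone (−602 counts against 582 in its partners, at flox/flox depth). For Akap2 the amounts were 410 against −76.4. For Foxp1 and Hist2h2aa1 the intervals of the partners included 0. Sums with the partners were examined before this test, which replaced them because an abundant partner dilutes the ratio of a sum. What stays open is a difference in how reads of long 3′ UTRs were assigned in each library: the 104 genes with an annotated 3′ UTR had a median length of 2448.5 nucleotides, above every one of the matched random sets (middle range 1142.5 to 1853.5). Long 3′ UTRs are also sites of regulation, so a biological source remains open too, and Cipc (longest 3′ UTR 2698 nucleotides) and Sp1 (5375) are among these genes.

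The positions of the 9 lists that stood apart were set against a trend with GC content or transcript length. Bin medians of all tested genes lay between −0.04 and 0.04 over GC content and between −0.02 and 0.05 over length. After correction 8 of the 9 lists stayed outside the random lists on the same side, which argues against that trend as their whole cause. The endothelial list was the 1 that did not. Its median went from 0.13 (−0.01 to 0.23) to 0.12 (−0.01 to 0.21). Its percentile went from 98.1 to 97.3, just under the limit. The correction left most of the median in place, which argues against the trend as its main source. The list lay close to the limit before and after the correction, so whether it stands apart is uncertain. For the matrix genes, fewer cells of the fibroblast lineage may be a source: the progenitor markers, none of which is in the matrix list, had a median of −0.13 (−0.25 to 0.05), with the abundant markers Gsn and Dcn both at −0.12. The intervals of the progenitor and matrix medians (−0.46 to 0.14) overlap and both include 0, which leaves it open.

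Tmem63c, present in scKO alone, is the next gene downstream of Cipc on its strand. A change of at least 2-fold across the whole region is argued against by the other 14 tested genes within 500 kb, with a median of −0.038 (−0.15 to 0.32); Noxred1 (1.16, 0.0031 to 2.52, on 9 and 20 counts), Vipas39 and Ahsa1 had intervals above 0, so changes of single neighbours stay open. A transcript that runs from the altered Cipc locus into Tmem63c could give such counts (at least 40.8-fold higher against 3 counts), but counts per gene hold no reads across exon junctions, so this hypothesis stays open beside a response of Tmem63c to the genotype.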
